A study of Mus musculus with 6 samples.

How the data were processed

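RNA-seq counts of 3 NETs-treated and 3 control samples of mouse cells labelled BMDM were analysed. Total RNA was extracted with a commercial kit and made into strand-specific libraries, per the labels' protocols. The submitters' processing notes name HISAT2, DESeq2 and the genome builds rn6 (rat) and mm10 (mouse), without versions or roles. The gene identifiers in the deposited table are those of mouse genes. The counting program, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes may therefore not be parted. Genes with near-identical copies are uncertain, also where this is not repeated beside the gene.

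The authors deposited 1 table with 55401 genes. It holds the raw read count per gene and sample, per the file headers. It also holds normalised counts, a signal that equals the deposited count divided by 1 size factor per sample, as tested on the values. The authors' log2 fold changes, p-values and adjusted p-values stand in the same deposited table. The tests used the raw counts, and the authors' fold changes served as an alternative. Every column of per-sample values was used or compared.

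Samples were grouped by the treatment given in the labels. Total counts were 41830940, 42067235 and 44274445 in the control and 43686531, 41399865 and 39994613 in the NETs-treated libraries. Library pairs of the same group differed by more than sampling noise, with a chi-square per gene between 9.95 and 80.5, so every library counted as 1 sample. The biological coefficient of variation was 18.5%. PCR reads without molecular identifiers are not independent molecules, so limits from counts of 0 cover counting error only. Such limits use 3 counts over the 3 libraries of a group.

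The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 6 samples, two-sided, with TMM scaling and without covariates. The filter of edgeR on low counts (minimum count 10, minimum total 15) kept 15272 genes, which held 99.9% of all counts. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The SE of a log2 fold change was taken from the fitted value and its F statistic. CPM values were scaled by TMM and computed here from the deposited counts, and are given as mean ± SD over 3 samples. On counts simulated from these libraries for NETs-treated against control, with 14876 genes tested, 61% of genes changed 2-fold and 29% of genes changed 1.5-fold were recovered, 4 of 14682 unchanged genes were called, and the median log2 fold change of the 2-fold genes was 0.99. Of 20 unchanged lists 0 were called. The simulated genes varied independently of each other, so this does not show how camera treats lists whose members are correlated.

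In total 36 gene lists and 13 cell type marker lists were fixed in advance. Those with at least 3 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, and then with a correlation estimated per list. The directional test of fry was run beside it. Genes were named by a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 10 CPM, groups that did not overlap, and a symbol that is not a predicted gene, a clone or a pseudogene. Clone names made of letters and digits were left out by the same rule. From each gene list it took up to 4 called members with the largest change and up to 2 that moved against the majority, or the 2 most abundant members where none passed. From each cell type list it took the 3 most abundant and the 3 most changed members. Actb, Gapdh, Hprt, Tbp and Ppia were added as reference genes. Genes named outside this rule are marked as chosen after their values were seen, except those named only as an overlapping gene or in the test of an explanation.

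The alternatives fixed in advance were the size factors of DESeq2, scaling by library size only, upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of CPM of 1 in at least 3 samples, the replicate number as a block, leaving out each of the 6 samples in turn, and the authors' deposited table. For lists, the settings were the estimated correlation, fry, and lists without genes that stand in another list. A test planned for FPKM was not run, since the table used here holds counts. Corrections for transcript GC content and transcript length were added after seeing the data. They entered a lowess trend (span 0.3) of each library's log2 counts as an offset in edgeR. Lists were tested with camera on the corrected values first without and then with voom weights; both are reported. With a GC trend added to the simulated counts of NETs-treated against control, over 14876 genes, the correction raised the recovery of 2-fold genes from 40% to 63% and the unchanged genes called from 2 to 10. GC content, length and coordinates came from GENCODE M21 on GRCm38, the assembly also called mm10, where 98.1% of identifiers matched with their version and 99.5% without it. Coordinates count from 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

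All 37 genes of the mitochondrial chromosome were listed at 0 counts in every library, and whether that chromosome was in the alignment reference is not given in the sources used here, so the list of 13 mitochondrially encoded genes was not tested. The lists for fibroblasts, T and NK cells, B cells, mast cells and erythroid cells had fewer than 3 tested members and were not tested either. Values of some single genes are not reported here.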

Results

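Macrophage-lineage mouse cells that had been exposed to neutrophil extracellular traps (NETs, the webs of DNA and granule protein that neutrophils release) were compared by RNA-seq with unexposed cells. There were 3 NETs-treated and 3 control samples of wild-type genotype. The labels give the cell type as BMDM, bone marrow-derived macrophages, while the sample titles carry the name BV2, a mouse microglial line; which of these the cells were is left open here. The dose of NETs, the time of exposure, and whether the 3 samples of a group came from separate cultures or animals are not given in the sources used here, so p-values measure the spread between these samples, which may be technical. The total count per sample ran from 39994613 to 44274445, and 15272 of the 55401 listed genes had enough counts to be tested.

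The comparison asks which transcripts differ between NETs-treated and control cells. Among genes with a mean of at least 10 CPM, groups that did not overlap and a symbol that is not a predicted gene or clone, the inflammatory transcripts of Csf3, Il1b, Cxcl2 and Ptgs2 rose most. Transcripts of the unfolded protein response and the type I interferon response fell as groups. Those of the G2 and M phases of the cell cycle also fell, a call of camera in limma that was lost at an adjusted p = 0.112 with an estimated correlation. Of the tested genes, 3896 were higher and 4155 lower in NETs-treated cells, together 52.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). At least a 2-fold change was found for 2947 genes, of which 1128 were higher and 1819 lower. The 3 samples of one group lay entirely above those of the other for 62.4% of the tested genes, where chance gives 10% for 3 against 3. The median log2 fold change over all tested genes was -0.02.

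**Figure D1:**
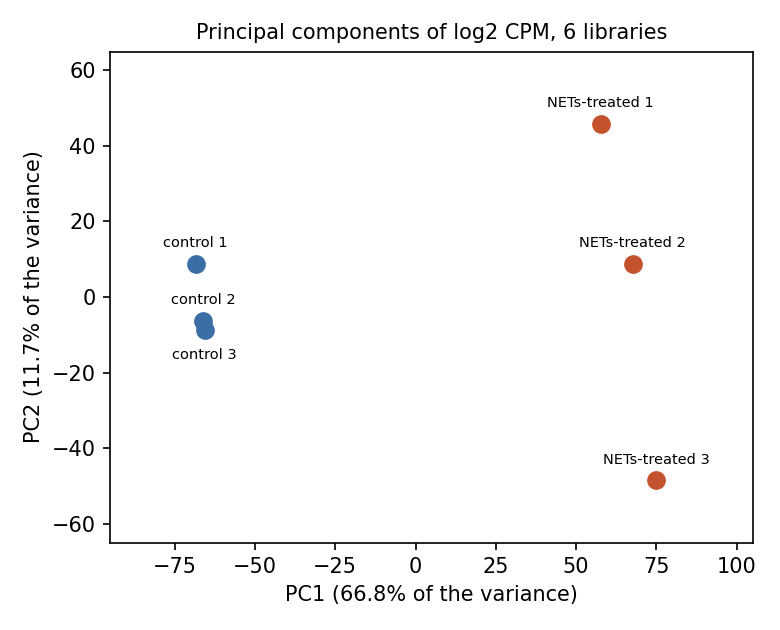
Each point is 1 library, placed by the first (horizontal axis) and second (vertical axis) principal component of log2 CPM over the 15272 tested genes, in the units of the component scores, with control in blue and NETs-treated in orange. The first component, with 66.8% of the variance, parts the groups, and the second, with 11.7%, spreads the NETs-treated libraries from -48.5 to 45.9 while the control libraries stay between -8.72 and 8.76.

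The NETs-treated libraries differed more among themselves than the control libraries did. The median SD of log2 CPM over genes was 0.20 among the NETs-treated and 0.12 among the control libraries.

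Csf3, which encodes the granulocyte growth factor G-CSF, showed the largest rise among the named genes with a mean of at least 10 CPM. It went from 0.861 ± 0.421 CPM in control to 709 ± 43.4 CPM in NETs-treated cells (SD, n = 3 each). Its log2 fold change was 9.67 ± 0.27 (SE), with an adjusted p of 1.45e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Csf3 (ENSMUSG00000038067.2) lies on chromosome 11 from 98701263 to 98703629 in GRCm38. Il1b, the gene of the cytokine interleukin-1 beta, rose from 1.05 ± 0.455 to 86.4 ± 6.11 CPM. This gene (ENSMUSG00000027398.13) spans 129364570 to 129371139 on chromosome 2. Cxcl2, a chemokine that attracts neutrophils, rose from 37.2 ± 0.571 to a mean of 1228 CPM, a log2 fold change of 5.05 ± 0.07 (SE). It (ENSMUSG00000058427.10) spans 90903871 to 90905938 on chromosome 5. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from a control mean of 19.4 CPM to 593 ± 73.5 CPM, a log2 fold change of 4.93 ± 0.12, and this gene (ENSMUSG00000032487.8) spans 150100031 to 150108227 on chromosome 1.

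Odc1, the enzyme of the first step of polyamine synthesis, reached 6542 ± 21.7 CPM from 486 ± 6.37 CPM, a log2 fold change of 3.75 ± 0.05 (SE). The zinc-finger transcription factor gene Klf2 rose from 6.10 ± 0.957 to 94.7 ± 31.4 CPM. Rab11fip1, which encodes a Rab11-binding protein of recycling endosomes, rose 13.2-fold, and Ccrl2, a receptor that binds chemerin, rose 11.2-fold. Tm4sf1, a membrane protein gene, rose 12.4-fold, while Phlda1 and Fam71f2 each rose 10.9-fold. A second Fam220a identifier (ENSMUSG00000118332.1) rose 12.4-fold, with 6.09, 36.6 and 34.6 CPM in the NETs-treated libraries. The overlapping first Fam220a identifier, chosen after its values were seen, had 29.4, 1.60 and 1.79 CPM in the same libraries, so the split of reads between them is uncertain.

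Among the genes that fell, Gpr183, a receptor for oxysterols that guides cell migration, went from 28.0 ± 2.78 to 0.413 ± 0.124 CPM. Its log2 fold change was -6.08 ± 0.21 (SE; adjusted p = 3.15e-07, edgeR with Benjamini-Hochberg adjustment), and the gene (ENSMUSG00000051212.8) spans 121952551 to 121965195 on chromosome 14. Ddit3, which encodes the stress transcription factor CHOP, went from 132 ± 7.58 to 4.81 ± 0.871 CPM; the annotation has a second Ddit3 identifier over the same stretch, which leaves a share of its reads uncertain. Plau, the gene of the protease urokinase, went from 447 ± 7.67 to 18.3 ± 1.45 CPM, a log2 fold change of -4.61 ± 0.08 (SE). Hdac9, a histone deacetylase gene, fell with a log2 fold change of -4.54 ± 0.24, and the immediate early transcription factor gene Egr3 with -4.32 ± 0.15. Cped1 had a log2 fold change of -4.31 ± 0.27, and Sla, which encodes a Src-like adaptor protein, of -4.21 ± 0.23. The transporter gene Abca9 had -3.88 ± 0.13, Efr3b had -3.85 ± 0.19, and Nos1, the neuronal nitric oxide synthase gene, had -3.82 ± 0.13. Nav2 went from 157 ± 1.12 to 11.2 ± 1.49 CPM and overlaps Gm2788 on its strand. Pakap, whose annotation overlaps a second Pakap identifier, had 16.0, 0.748 and 0.0255 CPM in the NETs-treated libraries against 93.1 ± 13.9 in control, so its size is uncertain.

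**Figure D2:**
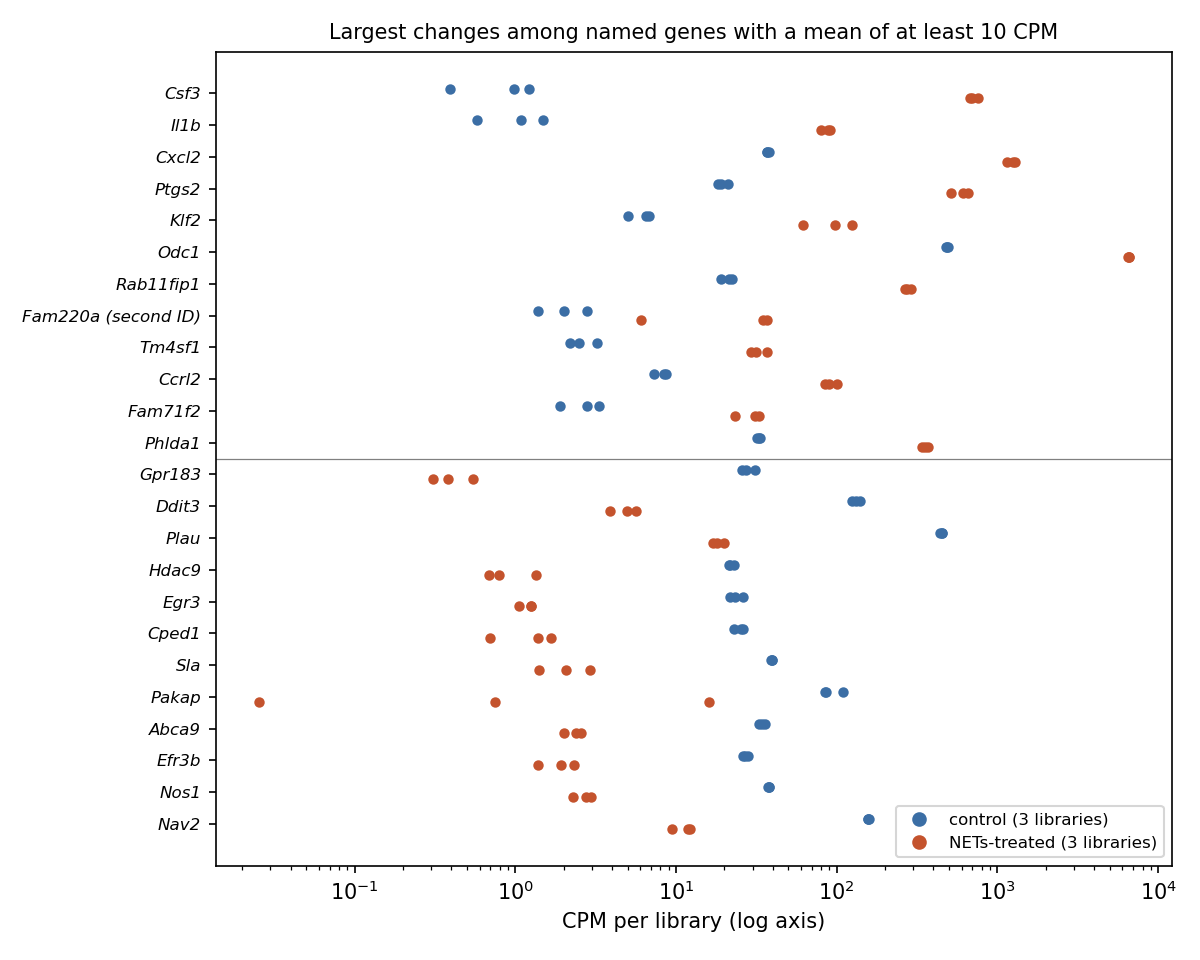
Each row is a gene and each point the CPM of 1 library on a log axis, with 3 control libraries in blue and 3 NETs-treated libraries in orange; above the line are the 12 largest rises and below it the 12 largest falls among called genes with a mean of at least 10 CPM, groups that did not overlap and a symbol that is not a predicted gene or clone. The groups do not overlap in any row, and the NETs-treated points lie furthest apart for Pakap, from 0.0255 to 16.0 CPM.

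The gene lists described next were fixed before the data were examined. Each list was compared with all other genes by camera in limma with a preset correlation of 0.01 between genes. Of 43 lists with at least 3 tested members, 18 passed at a Benjamini-Hochberg adjusted p under 0.05, of which 5 were higher and 13 lower. With the correlation estimated from the data, only the unfolded protein response and the type I interferon-stimulated genes passed. For the efferocytosis (-0.0630), osteoclast (-0.0613), classical activation (-0.0399), autophagy (-0.0314) and macrophage (0.00388) lists, the estimate lay below the preset 0.01. Correlation between members is therefore not what ended these calls. The other lists that lost their call had estimates above 0.01. However, the adjusted p of the unfolded protein response also rose, from 2.51e-10 to 0.0356, though its estimate was -0.0420. Estimating the correlation thus raised p-values where the correlation itself was lower than preset. What ended the other calls can therefore not be told from their estimates. Counts of members are from edgeR over all genes tested, and wherever a count adjusted over the list alone differed, it is given too.

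Transcripts of the unfolded protein response, which encode the chaperones and degradation factors of the endoplasmic reticulum, fell together. Of 22 tested members 19 fell and 0 rose, with a median log2 fold change of -1.30 (camera in limma, adjusted p = 2.51e-10, and adjusted p = 0.0356 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 3036 ± 73.8 to 640 ± 39.0 CPM, a log2 fold change of -2.25 ± 0.06 (SE). Herpud1, a factor in the degradation of misfolded proteins, went from 270 ± 12.7 to 34.7 ± 2.89 CPM. Sdf2l1 had a log2 fold change of -2.37 ± 0.10, and the co-chaperone gene Dnajc3 of -2.10 ± 0.10.

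The related list of ATF4 targets and amino acid response genes had 19 of 25 tested members lower and 3 higher. Camera gave an adjusted p of 2.31e-05, and an adjusted p of 0.159 with an estimated correlation. Besides Ddit3, the pseudokinase gene Trib3 went from 145 ± 10.4 to 16.7 ± 1.41 CPM, and Chac1, which encodes a glutathione-degrading enzyme, with a log2 fold change of -3.16 ± 0.18. Against that direction, Slc7a11, the cystine transporter gene, rose from 229 ± 10.9 to 649 ± 81.3 CPM, and the transcription factor gene Cebpb rose with a log2 fold change of 1.25 ± 0.13.

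The type I interferon-stimulated genes, the antiviral genes that interferon switches on, fell as a group. Of 37 tested members 31 fell and 0 rose (32 fell adjusted over the list alone), with a median log2 fold change of -1.68. Camera gave an adjusted p of 4.36e-10, and an adjusted p of 0.0356 with an estimated correlation. Cmpk2 went from 6.92 ± 1.57 to 0.225 ± 0.142 CPM and Ifit1 was at 3.07 ± 0.394 CPM in control and at 0.0941, 0 and 0 CPM in the NETs-treated libraries, so without NETs-treated replicate 1 that group is at 0. Ifit3b was at 0 in all NETs-treated libraries and 0.536 ± 0.224 CPM in control, at least 21.8-fold lower against a floor of 3 counts over the group.

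MHC class I presentation genes had 15 of 18 tested members lower and 1 higher (camera adjusted p = 8.90e-05, and adjusted p = 0.112 with an estimated correlation). The immunoproteasome gene Psmb9 had a log2 fold change of -1.98 ± 0.17, and the peptide transporter gene Tap1 of -1.58 ± 0.11. B2m, the light chain of the class I molecule, rose by a log2 fold change of 0.27 ± 0.07, a call that was lost without control replicate 1 or NETs-treated replicate 2 and with scaling by library size only. Among the genes that sense nucleic acids, 10 of 17 tested members fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.0340, and adjusted p = 0.315 with an estimated correlation). This list's call was also lost under 5 other settings, with camera's adjusted p between 0.0531 and 0.0755. The endosomal receptor gene Tlr7 went from 219 ± 17.2 to 84.1 ± 8.92 CPM and its chaperone gene Unc93b1 from 162 ± 4.81 to 61.0 ± 12.1 CPM, while the DNA sensor gene Aim2 rose from 55.2 ± 3.50 to 104 ± 3.26 CPM and the kinase gene Tbk1 from 55.8 ± 2.88 to 112 ± 6.50 CPM.

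The list of feedback regulators of NF-kB rose together. It holds genes that this transcription factor switches on, many of which restrain or extend its activity. Others in it, such as the cyclooxygenase gene Ptgs2, its most changed member, are targets with another function, so the rise is not one of regulators alone. Of 24 tested members 20 rose and 0 fell, with a median log2 fold change of 1.11 (camera adjusted p = 3.71e-10, and adjusted p = 0.112 with an estimated correlation). The adaptor gene Traf1 rose from 5.22 ± 0.563 to 50.2 ± 4.87 CPM. The inhibitor gene Nfkbie had a log2 fold change of 2.69 ± 0.18, and the ribonuclease gene Zc3h12a of 2.65 ± 0.14. Classical activation markers, genes of the inflammatory macrophage state, had 7 of 10 tested members higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.159 with an estimated correlation). Cd80, a ligand that costimulates T cells, rose from 15.7 ± 1.32 to 107 ± 1.79 CPM, and Acod1, the enzyme that makes itaconate, from 227 ± 4.69 to 864 ± 60.8 CPM. Without the members that stand in another list too, such as Ptgs2, this list gave an adjusted p of 0.169.

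The cytokine and chemokine lists moved in both directions and did not pass. Of 17 tested cytokine genes 7 rose and 5 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.725, and adjusted p = 0.822 with an estimated correlation). The list's median log2 fold change was -0.39 and its mean 1.06, with the direction of the test higher. Il6 rose from 0.928 ± 0.199 to 12.7 ± 1.14 CPM and Lif, a cytokine of the same family, from 3.93 ± 0.669 to 34.4 ± 0.504 CPM. Csf1, the growth factor of macrophages, went from 215 ± 13.3 to 57.5 ± 6.39 CPM, and Tnfsf9 from 106 ± 2.82 to 45.8 ± 5.14 CPM. Of 12 tested chemokine genes 4 rose and 4 fell (camera adjusted p = 0.995, and adjusted p = 0.996 with an estimated correlation), with a median of -0.12, a mean of 0.74 and a test direction of higher. This median was -0.19 with scaling by library size only and -0.04 with correction for GC content, which was added after seeing the data. Cxcl3, a chemokine that attracts neutrophils, was at 0, 0 and 0.0441 CPM in the control libraries and 5.24 ± 0.933 CPM in NETs-treated cells. Ccl2, which attracts monocytes, had a log2 fold change of -0.87 ± 0.09, and Cxcl10, an interferon-responsive chemokine gene, went from 2.23 ± 0.557 to 0.532 ± 0.0762 CPM.

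Genes of the G2 and M phases, which run mitosis, had 26 of 28 tested members lower and 0 higher (27 lower adjusted over the list alone; median log2 fold change -0.97, camera adjusted p = 2.51e-10, and adjusted p = 0.112 with an estimated correlation). The cyclin gene Ccnb2 went from 70.8 ± 5.17 to 21.1 ± 1.34 CPM, and Ccna2 from 73.0 ± 4.68 to 24.2 ± 0.496 CPM. The mitotic kinase gene Plk1 had a log2 fold change of -1.47 ± 0.13. The genes of S phase and DNA replication went both ways, with 9 of 30 higher and 10 lower (9 and 11 adjusted over the list alone; camera adjusted p = 0.782, and adjusted p = 0.865 with an estimated correlation; median -0.10, or -0.18 with scaling by library size only and -0.01 with correction for GC content, mean 0.0029 and a test direction of lower). The cyclins that open S phase rose, Ccne2 from 9.45 ± 0.269 to 26.8 ± 2.51 CPM and Ccne1 with a log2 fold change of 1.14 ± 0.11, while the thymidine kinase gene Tk1 had -0.89 ± 0.10. Of 10 tested members of the list of replication-dependent histones 4 fell and 0 rose (camera adjusted p = 0.211, and adjusted p = 0.419 with an estimated correlation), H1f2 among them with -1.78 ± 0.10. The 4 include H1f0, with a log2 fold change of -1.95, whose linker histone is in fact made independently of replication. They also include H1f4, a call lost in 7 settings (edgeR adjusted p up to 0.138).

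Lysosome and phagocytosis genes had 23 of 30 tested members lower and 3 higher (23 and 4 adjusted over the list alone; camera adjusted p = 3.83e-06, and adjusted p = 0.112 with an estimated correlation). Atp6v0d2, a subunit of the proton pump, went from 194 ± 12.2 to 35.4 ± 4.92 CPM. The antibody receptor genes Fcgr1, Fcgr4 and Fcgr2b had log2 fold changes of -2.34 ± 0.13, -1.91 ± 0.16 and -1.37 ± 0.07, while the lysosomal membrane gene Lamp2 rose from 740 ± 41.9 to 1421 ± 318 CPM. Of 12 tested efferocytosis genes, which serve the uptake of dead cells, 8 fell and 2 rose (camera adjusted p = 0.01, and adjusted p = 0.159 with an estimated correlation). The receptor gene Mertk went from 33.5 ± 1.38 to 4.86 ± 0.626 CPM, Axl was at 0 in the NETs-treated libraries and at least 27.4-fold lower than the 0.676 ± 0.0729 CPM of control, and the integrin gene Itgav rose from 223 ± 8.58 to 792 ± 106 CPM. Autophagy genes had 10 of 19 tested members higher and 4 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.159 with an estimated correlation). Wipi1 rose with a log2 fold change of 1.78 ± 0.15 and the initiating kinase gene Ulk1 with 1.06 ± 0.09.

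Glycolysis and HIF-1 target genes had 15 of 27 tested members lower and 4 higher (camera adjusted p = 0.0141, and adjusted p = 0.235 with an estimated correlation). The phosphofructokinase gene Pfkl went from 120 ± 11.9 to 33.3 ± 1.11 CPM, the pyruvate dehydrogenase kinase gene Pdk1 from 205 ± 4.46 to 64.1 ± 4.84 CPM, and Egln3, an oxygen-sensing hydroxylase, from 277 ± 1.39 to 102 ± 1.14 CPM. In camera without voom weights, added after seeing the data, this call was lost with correction for GC content (adjusted p = 0.0742) or for transcript length (adjusted p = 0.0568). Hif1a itself rose with a log2 fold change of 0.62 ± 0.10. Txnip, a gene that responds to glucose and binds thioredoxin, rose from 130 ± 9.62 to 591 ± 2.09 CPM. Nuclear genes of the mitochondrial respiratory chain had 6 of 28 tested members higher and 9 lower (7 and 9 adjusted over the list alone; camera adjusted p = 0.840, and adjusted p = 0.921 with an estimated correlation). Cytosolic ribosomal protein genes had 22 of 38 tested members higher and 0 lower, by a median log2 fold change of 0.19, or 0.12 with scaling by library size only (camera adjusted p = 0.00334, and adjusted p = 0.235 with an estimated correlation). How reads of near-identical gene copies were counted is not given, so a shift this small is uncertain.

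**Figure D3:**
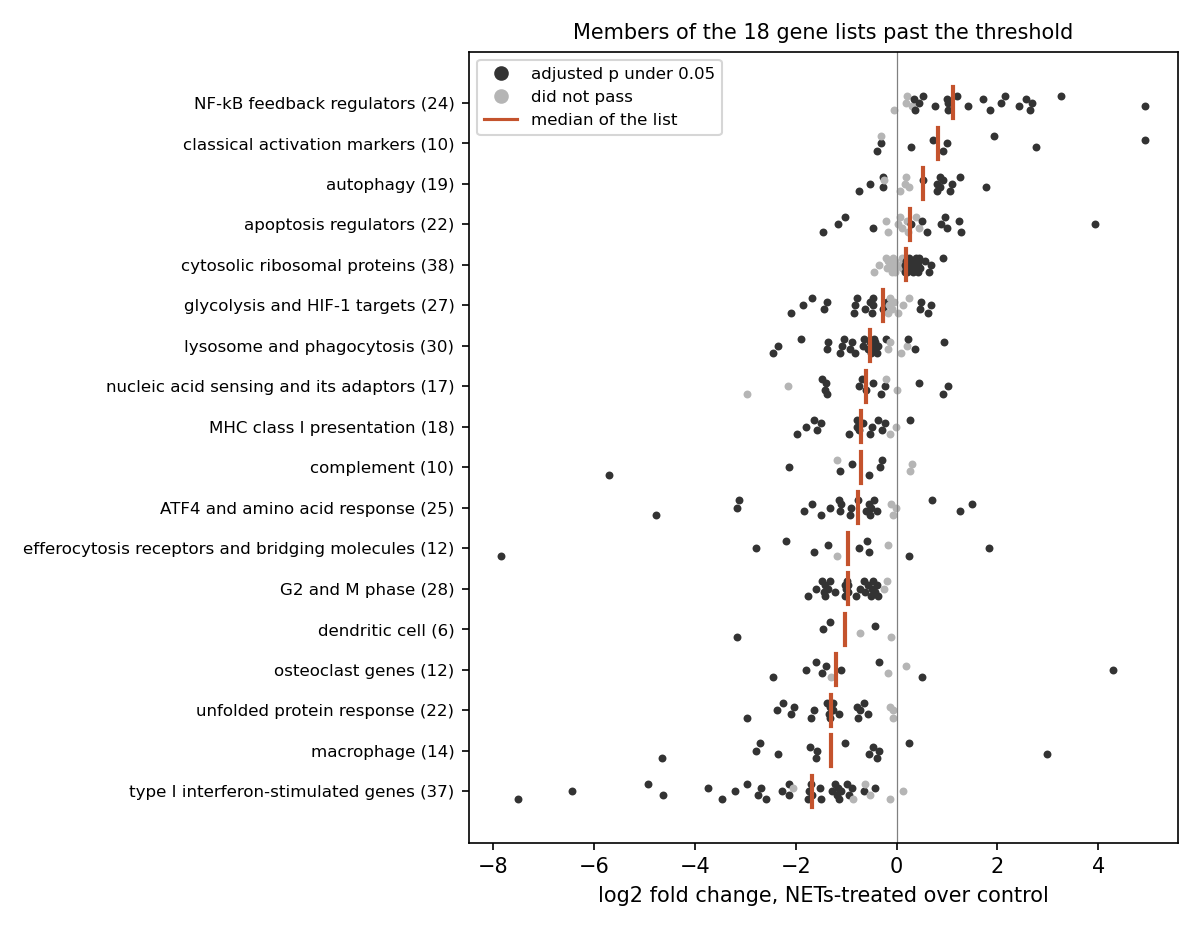
Each point is 1 tested gene of a list, placed by its log2 fold change of NETs-treated over control on the horizontal axis, for the 18 lists that passed; dark points are genes with an adjusted p under 0.05, grey points the others, the orange bar is the list's median, and the number of tested members stands in brackets. The medians run from -1.68 for the type I interferon-stimulated genes to 1.11 for the NF-kB feedback regulators.

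Of 14 tested macrophage markers 12 fell and 2 rose (camera adjusted p = 0.00110, and adjusted p = 0.112 with an estimated correlation). Lyz2, the macrophage lysozyme gene, was at 2978 ± 81.2 CPM in control and 3526 ± 144 CPM in NETs-treated cells. Cd14, a co-receptor for bacterial lipopolysaccharide, rose from 691 ± 6.08 to 5442 ± 85.7 CPM, a log2 fold change of 2.98 ± 0.05. The lipase gene Lpl went from 2058 ± 102 to 680 ± 86.4 CPM, and the transcription factor gene Maf from 4.39 ± 0.259 to 0.172 ± 0.0626 CPM. Of 9 tested microglia markers 6 fell and 2 rose (camera adjusted p = 0.211, and adjusted p = 0.350 with an estimated correlation), with Trem2 from 190 ± 3.24 to 88.4 ± 2.72 CPM. Some genes were chosen after their values were seen because of the conflict between title and cell type. The complement gene C1qa had 0 to 3 counts per library, C1qb had 5 to 32, the mannose receptor gene Mrc1 had 11 to 49, and Ccr2 had 0 to 5. The microglia marker Tmem119 was at 1.44 ± 0.562 CPM in control and 5.04 ± 0.459 CPM in NETs-treated cells, and Sall1 had 0 counts in every library, which allows up to 0.0228 CPM in the control and 0.0246 CPM in the NETs-treated group (3 counts over the group, for counting error alone).

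Of 8 tested neutrophil markers 2 rose and 5 fell (camera adjusted p = 0.553, and adjusted p = 0.627 with an estimated correlation). Lcn2, an iron-binding protein that macrophages make too, rose from 32.4 ± 2.30 to 146 ± 12.6 CPM, while Mmp9 went from 96.3 ± 8.76 to 45.0 ± 3.92 CPM. The abundant granulocyte transcripts S100a9, Mpo, Ngp, Ltf and Ly6g, looked up after the other values were seen, had 0 counts in all 6 libraries, while S100a8, chosen in the same way, rose from 2.68 ± 0.591 to 11.7 ± 2.67 CPM. Of 6 tested dendritic cell markers 4 fell and 0 rose (5 fell adjusted over the list alone; camera adjusted p = 0.0333, and adjusted p = 0.235 with an estimated correlation), among them the integrin gene Itgax from 152 ± 4.17 to 55.2 ± 0.978 CPM and Irf8 from 75.5 ± 5.26 to 30.1 ± 6.88 CPM. Without members shared with another list, the dendritic cell list gave an adjusted p of 0.183 in camera, and with correction for GC content without voom weights 0.0627. Among genes often used as references, Actb rose with a log2 fold change of 0.67 ± 0.06 and Hprt fell with -0.37 ± 0.11, a call lost without control replicate 2 or 3 or NETs-treated replicate 2 and with correction for transcript length (edgeR, Benjamini-Hochberg adjusted p from 0.0619 to 0.101). Tbp had 0.20 ± 0.15 (adjusted p = 0.279) and Ppia -0.47 ± 0.20 (adjusted p = 0.0797, edgeR with Benjamini-Hochberg adjustment; 0.0357 without NETs-treated replicate 3). Gapdh was listed at only 21.7 ± 7.82 and 19.4 ± 3.10 CPM, and since the genome holds many near-identical Gapdh copies, its value is uncertain.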

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

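The corrections for GC content and transcript length, with and without voom weights in the list test, were chosen after seeing the data. The counts of 3896 genes higher, 4155 lower and 2947 changed at least 2-fold stayed within 1.5 times their value under all 17 alternatives that test genes. Leaving out 1 sample gave 3265 to 4137 genes higher, 3451 to 4360 lower, 2702 to 3213 at least 2-fold, and 16 to 18 lists. Of the 8051 called genes, 6580 (without control replicate 3) to 7546 (without NETs-treated replicate 1) were called again with the same sign when 1 sample was left out, and 0 with the opposite sign. The authors' deposited table called 7770 of them with the same sign. Scaling by library size only gave 3351 higher and 4636 lower, and moved the median log2 fold change of all genes by -0.08. With the GC correction 4390 genes were higher and 4076 lower. The 18 lists became 2 with camera's correlation estimated and 39 with fry, which by its construction does not compare a list with other genes. With fry, 3 lists without a call in camera passed in the opposite direction: inflammasome and pyroptosis (adjusted p = 0.0107), matrix proteases and remodelling (adjusted p = 5.26e-05) and sphingolipid and eicosanoid enzymes (adjusted p = 0.0489). The cause was not tested. The list test on corrected values was first run without voom weights, where 13 lists passed with the GC correction and 17 with the length correction. It was then replaced, after these counts were seen, by the form with voom weights, where 18 passed with either, because the first form changed weights and correction together. Without weights, the GC correction ended 5 calls (nucleic acid sensing, glycolysis and HIF-1 targets, apoptosis regulators, osteoclasts and dendritic cells) and the length correction 2 (nucleic acid sensing, glycolysis and HIF-1 targets). Over the 15 settings other than the estimated correlation and fry, both forms included, 11 of the 18 called lists kept their call; the other lists were those 5, complement and classical activation.

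Of 205 called genes that the naming rule allows, 189 kept their sign and call under every alternative that gave a value, and 0 reversed. The 16 others included Ahsa1, B2m, Bst2, Ccl24, F13a1, H1f4, Hprt, Ifi30, Irf1, Irf5, P2ry12, Prtn3, Rac1, Tfe3 and Vcan, with adjusted p among these of up to 0.154 (Irf1; edgeR, DESeq2 and limma, Benjamini-Hochberg). Ppia gained a call without NETs-treated replicate 3. The simulated recovery of 29% at a 1.5-fold change came from counts in which only 100 genes changed 1.5-fold and 100 genes 2-fold. In the data 52.7% of the tested genes were called, which makes the adjusted p less strict. The simulated recovery therefore does not give the recovery of this comparison, and how many small changes 3 samples per group miss is not known.

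With the replicate number as a block, 3896 genes were higher and 4209 lower, 2858 changed at least 2-fold and 18 lists passed. Deviations of same-numbered samples correlated at 0.12, 0.03 and 0.07 over genes, so the numbers were not taken to pair samples. Each sample correlated best with its own number, a hint from the data and not from the design.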

Other observations

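The tests of carried-over neutrophil RNA, of GC content as the whole cause of the spread between libraries, and all values corrected for GC content or transcript length were chosen only after the results were seen. Of 15 tested LXR and lipid efflux genes 4 rose and 8 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.336, and adjusted p = 0.639 with an estimated correlation). The cholesterol exporter gene Abca1 rose from 18.1 ± 1.16 to 144 ± 13.9 CPM (SD, n = 3), while the fatty acid binding protein gene Fabp4 had a log2 fold change of -1.49 ± 0.07 (SE). Cholesterol synthesis genes had 9 of 23 higher and 4 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.471, and adjusted p = 0.537 with an estimated correlation), with Fdft1 at a log2 fold change of 1.23 ± 0.08 (SE). Of 14 heat shock genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.104, and adjusted p = 0.419 with an estimated correlation), and Hsph1 rose from 104 ± 2.02 to 640 ± 14.8 CPM. NRF2 and antioxidant genes had 8 of 21 higher and 8 lower (camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation; median -0.05 and mean -0.05 with a test direction of higher, and the median turns above 0 with correction for transcript length), with Prdx1 at 1.02 ± 0.07 and Hmox1 at -1.30 ± 0.11. Iron handling genes had 6 of 15 higher and 7 lower (camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation), and the iron exporter gene Slc40a1 went from 94.1 ± 5.69 to 25.7 ± 1.63 CPM. Of 23 p53 target genes 7 rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.574, and adjusted p = 0.627 with an estimated correlation). Apoptosis regulators had 9 of 22 higher and 4 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.0427, and adjusted p = 0.235 with an estimated correlation), a call lost in 6 other settings with adjusted p between 0.05 and 0.135, without NETs-treated replicate 2 or 3 among them. Bcl2l11, a gene that promotes cell death, rose with a log2 fold change of 1.24 ± 0.07 and Bcl2, which opposes it, had -1.16 ± 0.09.

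Surface Toll-like and lectin receptors had 5 of 16 higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation; median 0.21, or 0.14 with scaling by library size only and 0.04 with correction for GC content, mean -0.03, test direction higher), with Clec4e at a log2 fold change of 1.98 ± 0.10 (SE) and Clec7a at -2.87 ± 0.13. Inflammasome genes had 5 of 14 higher and 7 lower (camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation; median -0.41, mean 0.15, test direction lower). Alternative activation markers had 3 of 13 higher and 9 lower (camera adjusted p = 0.0676, and adjusted p = 0.274 with an estimated correlation; 0.0415 with correction for transcript length without voom weights), with Tgm2 at 2.84 ± 0.09 and Flt1 at -2.68 ± 0.08. Of 11 MHC class II and costimulation genes 5 rose and 2 fell (camera adjusted p = 0.202, and adjusted p = 0.333 with an estimated correlation), with Cd83 at 2.10 ± 0.08. Complement genes had 7 of 10 lower and 0 higher (camera adjusted p = 0.0217, and adjusted p = 0.235 with an estimated correlation), and C3ar1 had -2.13 ± 0.08; the call was lost without NETs-treated replicate 3 (adjusted p = 0.0529) and with the stricter filter (adjusted p = 0.0553). Osteoclast genes had 7 of 12 lower and 2 higher (camera adjusted p = 0.0333, and adjusted p = 0.203 with an estimated correlation), with Dcstamp at -1.80 ± 0.10, and an adjusted p of 0.193 without members shared with another list and of 0.0841 with correction for GC content without voom weights. Migration and adhesion receptors had 9 of 16 lower and 2 higher (camera adjusted p = 0.0676, and adjusted p = 0.235 with an estimated correlation; 0.0466 with correction for GC content). Matrix protease genes had 9 of 19 higher and 5 lower (camera adjusted p = 0.956, and adjusted p = 0.955 with an estimated correlation); Mmp3 was at 0 in control and at least 58.1-fold higher in NETs-treated cells. Immediate early genes had 12 of 26 higher and 8 lower (camera adjusted p = 0.284, and adjusted p = 0.553 with an estimated correlation), and Dusp5 rose from 45.9 ± 1.57 to 269 ± 8.11 CPM. Eicosanoid and sphingolipid enzymes had 4 of 14 higher and 7 lower (camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation; median -0.19, mean 0.08, test direction lower). Of 5 monocyte markers 2 rose and 2 fell (camera adjusted p = 0.782, and adjusted p = 0.822 with an estimated correlation), of 5 platelet markers 1 rose and 2 fell (0.725, and adjusted p = 0.794 with an estimated correlation), of 3 endothelial markers 1 rose and 1 fell (0.913, and adjusted p = 0.921 with an estimated correlation), and of 3 markers of astrocytes, neurons and oligodendrocytes 2 fell (0.514, and adjusted p = 0.627 with an estimated correlation). The untested lists held 2 fibroblast and 2 erythroid genes and 1 mast cell gene with enough counts, none of which passed, and the T cell gene Lck and the B cell gene Ighm, which fell from 3.06 ± 0.901 to 1.03 ± 0.479 CPM and from 11.7 ± 0.940 to 0.699 ± 0.0583 CPM.

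Values from the mitochondrial genome stood out. While its own 37 genes had 0 counts, 4 copies of mitochondrial sequence on chromosome 1 (Gm28437, Gm10925, Gm28661 and Gm29216, between 24613189 and 24616197 in GRCm38), chosen after their values were seen, took 1.05% to 1.24% of all counts in the control and 1.65% to 2.37% in the NETs-treated libraries. Whether the mitochondrial chromosome was part of the alignment reference is not given in the sources used here. It is therefore open whether these reads came from mitochondrial transcripts. Exactly 0 counts for all 37 genes, in libraries of 39994613 to 44274445 counts, argue against these 0 counts as measured levels.

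The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split called 3896 genes higher and 4155 lower, and 2947 at least 2-fold, where the highest of the other splits called 0 genes by edgeR in each count (no other tool was run on the splits). At an unadjusted p under 0.05, the real split had 8899 genes and the highest of the other splits 152. The real split called 18 lists, where the highest of the other splits called 9. For each of these counts, 1 of the 10 splits, the real one, gave a result as large. Every other split put libraries of both treatments in each group. The difference between treatments then widens the spread within groups, so the low gene counts of those splits are not a measure of chance. Their contrasts also keep a part of the treatment difference, so the 6 to 9 lists they called are not one either.

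The fall of unfolded protein response and ATF4 genes with a rise of Txnip led to the hypothesis that more glucose was left to the NETs-treated cells at harvest, since a lack of glucose can switch these responses on in control cells. Arrdc4, a glucose-responsive gene regulated like Txnip and not looked at before, was named in advance as the test, and it rose with a log2 fold change of 2.12 (95% interval 1.91 to 2.34). Removing each library's GC trend left a share of 0.928 of the median log2 fold change of the 41 called members (from -1.15 to -1.06, with 40 still called with the same sign). This argues against the GC trend as the whole cause. The smallest share kept under other scalings was 0.990. Those scalings moved the median log2 fold change of all genes by only -0.0753 to 0.0129, too little to undo a median of -1.15. The scaling test therefore shows only that the choice among these scalings does not make the fall. Since Arrdc4 is regulated like Txnip, whose rise had already been seen, its rise largely repeats that observation and does not measure glucose. The hypothesis stays open, as Arrdc4 and Txnip also respond to other changes in energy metabolism. A direct effect of the NETs, which the design names, was not parted from a difference in glucose.

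The rise of Csf3, Il1b, Cxcl2 and NF-kB regulators beside a fall of interferon-stimulated genes was weighed next. RNA carried over from mouse neutrophils in the NETs is argued against by S100a9, S100a8, Camp, Ngp and Ltf, whose summed level was at most 1.13% of the rise of Cxcl2 in any NETs-treated library (8.89 to 14.1 CPM against 1119 to 1245 CPM). Nearly all of that sum was S100a8, and the 0 counts of S100a9, Ngp and Ltf were known beforehand. The source of the NETs is not given in the sources used here, so RNA from neutrophils of another species was not tested. The GC trend is argued against as well, as removing it kept a share of 0.961 of the median of the 31 called interferon-stimulated genes, 29 of them still called with the same sign. Raised cAMP and CREB signalling may contribute but cannot be told apart from other causes. Of 5 tested CREB targets named in advance, 3 rose, with log2 fold changes of 0.40 (Per1), 0.65 (Sik1) and 0.52 (Nfil3). The other 2 fell by more, Rgs2 with -2.13 and Pde4d with -2.51. Their median log2 fold change was 0.40, but the targets did not move together. The effect of NETs on the cells, through whichever receptor, stays open and was not tested apart from the preparation they came in.

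The NETs-treated libraries were spread more widely than the control libraries. Over genes, which are not independent replicates, Spearman's rho of GC content with the log2 ratio of NETs-treated replicate 3 over replicate 1 was -0.393, and that of transcript length was 0.0953, below the bound of 0.1 set in advance for length playing no part. Other pairs of NETs-treated libraries had a rho with GC content of -0.329 (2 over 1) and -0.230 (3 over 2), and control pairs had -0.271 (2 over 1), -0.285 (3 over 1) and -0.0158 (3 over 2), so a GC trend between libraries is not particular to the wider group. GC content may be part of the spread and is argued against as the whole of it: after its trend was removed, the median SD of the NETs-treated libraries was still 1.60 times that of the control libraries (1.67 times before), and what else set them apart is open, with no biological explanation tested.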
